A study of Homo sapiens with 8 samples.

How the data were processed

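Total RNA of 22Rv1 cells was sequenced on an Illumina NovaSeq instrument, per the labels, in 4 control and 4 inhibitor-treated samples. The deposited values are whole-number counts per gene, 1 file per sample, which the authors made by aligning reads to hg38 and counting with featureCounts, per the series text and the submitters' processing notes. The authors then used DESeq2, per the same sources. The aligner, the annotation, the tool versions, strandedness, library kit and read filters are not given in the sources used here. If the counting ignored strand, reads of a gene and its antisense partner could not be told apart, so overlaps with expressed genes were looked up for MARK1 to MARK4, KLK3 and the genes with the largest rises and falls, and are stated beside them. Other genes were not examined for overlaps.

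Each file listed 58735 Ensembl gene identifiers, the same in all 8, and 0 lines named no gene. Symbols, coordinates and transcript GC content were taken from GENCODE release 44 on hg38, in which 58207 identifiers were found. The 528 not found held at most 0.0979% of a library's counts and stayed in the tests. Groups and replicate numbers were taken from the sample titles. Total counts ranged from 12672817 to 13386143 in controls and from 13517289 to 21271127 in treated samples. A chi-square comparison of counts over 14677 genes gave 1.736 to 10.811 per degree of freedom within groups, so every pair differed by more than sampling noise, and 38.905 to 53.965 between groups. Among controls, replicates 1 and 2 (1.761) and replicates 3 and 4 (1.736) were closer than the pairs across them (3.662 to 4.986).

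The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the group, which left 16452, libraries were scaled with TMM factors (0.96 to 0.968 in controls, 1.011 to 1.059 in treated samples), and glmQLFit with robust dispersion and glmQLFTest were run on the group alone. An adjusted p under 0.05 (Benjamini-Hochberg over all tested genes) was called. The common biological coefficient of variation was 7.2%. The standard error of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. Levels are given as CPM on the TMM scale, except the summed levels of marker lists, which are CPM of the unscaled total counts. An exact two-sided permutation test was used for single values of 4 against 4, for which the smallest p is 0.0286.

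Before the data were examined, the design, the alternatives, 46 gene lists written from general knowledge and the rule for genes named in the text were fixed. The rule took genes set by name, among them MARK1 to MARK4 and KLK3. It added the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM and libraries that did not overlap, and the 5 higher and 5 lower genes with the smallest p at that level. From each list it took up to 4 called members per direction with the smallest p, of which the text names some. Some genes and lists that were computed, 1 called list and the shortened lists among them, are not reported here. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the 45 lists tested. Camera compares a list with all other genes. It was repeated with an estimated correlation, and fry, which tests whether the genes of a list move one way without comparing them with other genes, was run beside it. Unless another count is given, the counts of genes called adjusted over the list alone differed from those over all genes by at most 2 in a direction.

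The procedure was tested on simulated counts with the means and library sizes of these samples, of which 16240 genes passed the filter. The test recovered 42.9% of genes changed 1.25-fold, 66.7% of those changed 1.5-fold, 93.9% at 2-fold and 100% at 4-fold, and called 0.069% of 16007 unchanged genes. Camera called a simulated set of 40 genes raised 1.25-fold and did not call an unchanged set of 40. Few simulated genes changed, whereas 58% of the tested genes were called in the data, so the recovery rates need not carry over. The simulated genes were drawn independently, so the camera check does not test the preset correlation.

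The alternatives were RLE, upper-quartile and total-count scaling, no filter and a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, dispersion without robust estimation, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a minimum log2 change of 1. Chosen after seeing the data were offsets that remove each library's trend on transcript GC content (known for 99.4% of tested genes), 1 surrogate variable from sva 3.50.0, thinning of all libraries to the lowest total, and 2 shortened lists. GC was examined because the log2 change had a Spearman rho of −0.188 with transcript GC content across genes, which are not independent replicates. All 8 files were used.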

Results

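RNA sequencing was performed on 22Rv1 cells, a human castration-resistant prostate cancer line. The 8 libraries formed 2 groups of 4. The control group received DMSO, the vehicle, and the other group received PCC0208017, described by the submitters as an inhibitor of the kinase MARK3. The total counts were 13218162, 13115520, 12672817 and 13386143 for control replicates 1 to 4, and 14218542, 21271127, 13517289 and 14080310 for inhibitor replicates 1 to 4. Each library held at least 1 count for between 25536 and 28294 genes. At this depth and spread, the median standard error of a log2 fold change was 0.096. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Dose and duration of the treatment are not given in the sources used here.

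The comparison of inhibitor with control asked which transcripts differ in 22Rv1 cells given this compound. MARK3 was not targeted in any other way and its activity was not measured here. Effects of MARK3 inhibition therefore cannot be told apart from other effects of the compound. Inhibitor-treated cells had lower levels of kallikrein and luminal prostate transcripts, of MYC and ribosome biogenesis genes, and of 47 of 48 genes of G1/S and DNA replication (adjusted p = 0.0545 with an estimated correlation). KLK3, which encodes prostate-specific antigen, was 26.8-fold lower, and the transcription factor gene MYC was 11.6-fold lower. DHRS2, which encodes a short-chain dehydrogenase/reductase, was 8.44-fold higher. Higher levels were found for 42 of 63 genes of G2/M and mitosis, 33 of 43 lysosomal, 21 of 34 interferon-responsive and 6 of 6 metallothionein and zinc-responsive genes, and these lists also lost their camera call with an estimated correlation (adjusted p = 0.494, 0.0545, 0.075 and 0.075). All fold changes below are inhibitor minus control on the log2 scale, given ± SE with n = 4 libraries per group, and all adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

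Of 16452 genes tested, 9549 (58%) differed between the groups, with 4897 higher and 4652 lower in inhibitor-treated cells. A change of at least 1 on the log2 scale was found for 698 higher and 1002 lower genes, and of at least 2 for 75 higher and 159 lower genes. The median absolute log2 change of the called genes was 0.525. In 8069 of the called genes (84.5%), all 4 inhibitor libraries lay beyond all 4 controls. This held for 51% of the tested genes, against 2.86% for chance groupings of 4 against 4. The first principal component, with 70.6% of the variance, separated the groups. With total counts in place of TMM factors the median change of all tested genes moved from 0.021 to 0.126 and the share of higher genes among the calls from 51.3% to 63.6%. Small changes are therefore stated relative to the TMM scale.

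**Figure D1:**
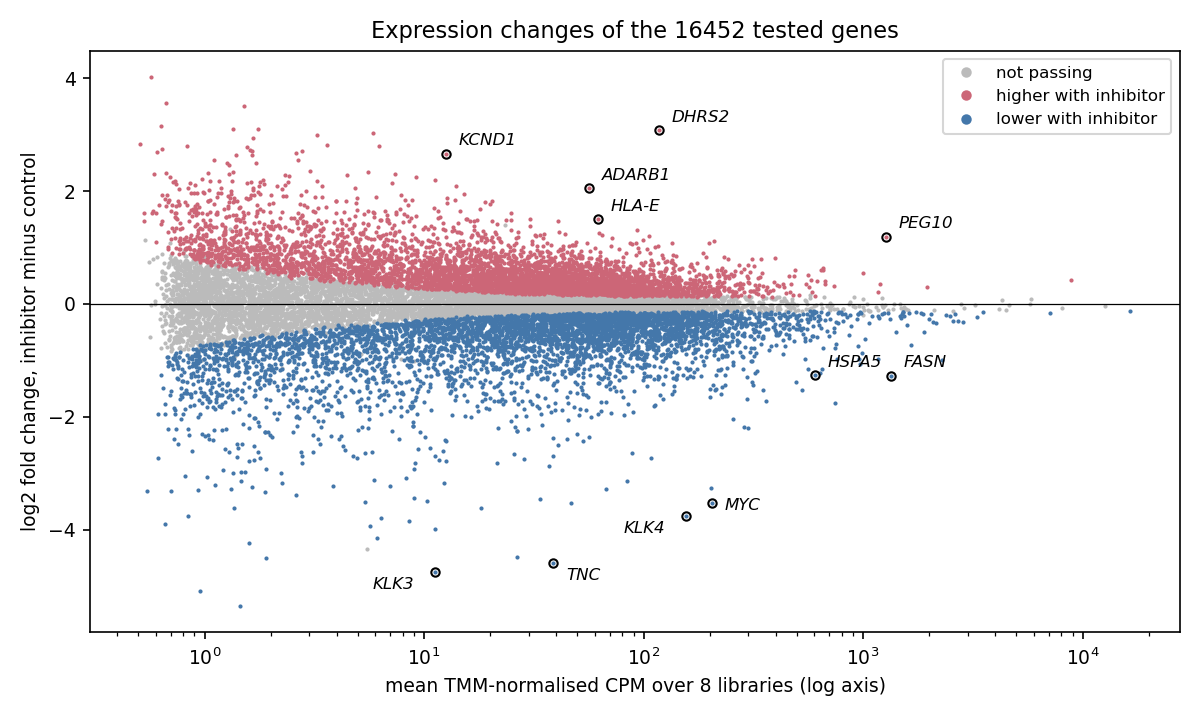
Log2 fold change (inhibitor minus control, vertical axis) against mean TMM-normalised CPM over the 8 libraries (horizontal log axis) for each of the 16452 tested genes. Red points are the 4897 genes higher and blue points the 4652 genes lower with the inhibitor at an adjusted p under 0.05, grey points did not pass, and circled genes are named. KLK3, TNC, KLK4 and MYC lie among the largest falls and DHRS2 among the largest rises.

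MARK3 mRNA itself was slightly higher in treated cells. MARK3 (ENSG00000075413; chromosome 14, 103385377 to 103503831, hg38, plus strand) rose from 77.99 ± 2.31 to 90.64 ± 2.29 CPM (counts scaled to a common library size; mean ± SD, n = 4), a log2 fold change of 0.22 ± 0.06 (adjusted p = 0.00287), with all 4 treated libraries above all controls. MARK1 rose from 12.47 ± 0.754 to 16.39 ± 1.77 CPM (0.40 ± 0.10, adjusted p = 0.00178). MARK4 went from 26.12 ± 2.71 to 31.96 ± 3.60 CPM (0.29 ± 0.09, adjusted p = 0.00749), with overlapping libraries, and its gene model overlaps several expressed genes, among them PPP1R37 and TRAPPC6A. MARK2 did not pass the test (0.03 ± 0.06, adjusted p = 0.741). An inhibitor of the protein need not change the mRNA, so these values do not check the labels. Across the list of MARK kinases and cell polarity genes, 11 of 33 tested members were higher, 7 were lower and 15 did not pass (camera adjusted p = 0.652), with 15 higher and 4 lower under total counts and 10 and 8 with RLE normalisation.

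Kallikrein and other prostate-expressed genes were among the largest falls. KLK3 (ENSG00000142515; chromosome 19, 50854915 to 50860764, plus strand) fell from 21.62 ± 1.94 to 0.819 ± 0.143 CPM (−4.74 ± 0.16, adjusted p = 4.01e-18), which corresponds to 244 to 298 counts per control library and 12 to 14 per treated library. The kallikrein genes KLK4 (−3.76 ± 0.08) and KLK2 (−3.45 ± 0.09), the protease gene TMPRSS2 (−3.53 ± 0.09) and PMEPA1, which encodes an inhibitor of TGF-beta signalling (−3.25 ± 0.06), fell in every treated library relative to every control. TMPRSS2 overlaps MX1 on the opposite strand, and whether the counting used strand is not given in the sources used here. HERC3 (0.70 ± 0.10) and NDRG1 (0.40 ± 0.07) rose.

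**Figure D2:**
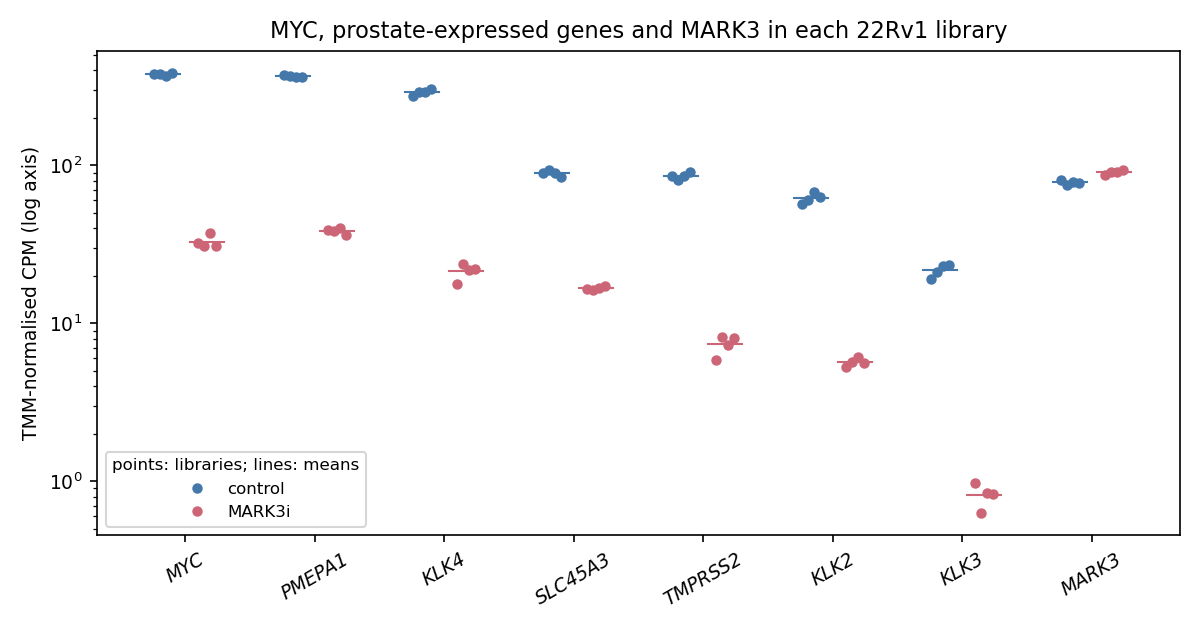
TMM-normalised CPM (vertical log axis) of MYC, PMEPA1, KLK4, SLC45A3, TMPRSS2, KLK2, KLK3 and MARK3 in each library, with blue points for the 4 control and red points for the 4 inhibitor libraries and a line at each group mean. All treated libraries lie below all controls for every gene shown except MARK3, for which they lie above.

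Luminal prostate markers fell as a group. Of 21 tested luminal markers, 16 were lower, 1 was higher and 4 did not pass, with a median of −1.05 (camera adjusted p = 2.58e-08; adjusted p = 0.0131 with an estimated correlation). SLC45A3, which encodes the prostate transporter prostein, changed by −2.42 ± 0.07. Among steroid-related genes, NR3C1, the glucocorticoid receptor gene, rose (1.20 ± 0.08, adjusted p = 8.27e-12), as did the coactivator gene NCOA1 (0.74 ± 0.07). The aldo-keto reductase genes AKR1C2 (−1.65 ± 0.07) and AKR1C3 (−0.92 ± 0.06) fell, although reads of these near-identical paralogs can be hard to assign.

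MYC and genes of ribosome biogenesis fell together. MYC (ENSG00000136997; chromosome 8, 127735434 to 127742951, plus strand) fell from 378.3 ± 8.55 to 32.8 ± 2.98 CPM (−3.53 ± 0.07, adjusted p = 4.75e-23). Of 41 tested members of the list of ribosome biogenesis and MYC target genes, which includes MYC, 40 were lower and 1 was higher, with a median of −0.87 (camera adjusted p = 4.05e-18; adjusted p = 0.00382 with an estimated correlation). NME1, a nucleoside diphosphate kinase gene (−1.91 ± 0.08), and the nucleolar protein genes MYBBP1A (−1.62 ± 0.06) and NOLC1 (2.83-fold lower) fell. The member that rose was NOP2 (0.75 ± 0.19), at only 2.58 ± 0.544 CPM in controls. Among 75 ribosomal protein genes, 42 were lower, 0 were higher and 33 did not pass, with a small median change of −0.15 (camera adjusted p = 0.000314; adjusted p = 0.754 with an estimated correlation). With total counts in place of TMM, 12 of these were lower and the median was −0.05. RPL35 (−0.31 ± 0.06, or −0.205 with total counts) was among those that fell.

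Genes of G1/S and DNA replication fell while genes of G2/M and mitosis rose. Of 48 G1/S genes, 47 were lower and 1 did not pass, and all 48 were lower when adjusted over the list alone (median −0.86, camera adjusted p = 1.95e-19; adjusted p = 0.0545 with an estimated correlation). Examples were the transcription factor genes E2F1 (−1.42 ± 0.06) and E2F2 (−1.45 ± 0.07) and the replicative helicase genes MCM3 (−1.31 ± 0.06) and MCM5 (−1.44 ± 0.06). Of 63 G2/M genes, 42 were higher, 6 were lower and 15 did not pass (median 0.29, camera adjusted p = 9.94e-05; adjusted p = 0.494 with an estimated correlation). With a GC adjustment of the counts the G2/M median was 0.184, with 37 genes higher and 10 lower. The spindle checkpoint kinase gene BUB1 rose by 0.83 ± 0.07, CKAP2 by 0.68 ± 0.07, the mitotic kinesin gene KIF20A by 0.67 ± 0.07 and the securin gene PTTG1 by 0.56 ± 0.06. The mitotic transcription factor gene FOXM1 (−0.34 ± 0.06) and the separase gene ESPL1 (−0.39 ± 0.07) fell. The mean log2 CPM of the G2/M list minus that of the G1/S list was −0.42 ± 0.01 in controls and 0.69 ± 0.04 in treated libraries (SD, n = 4; difference 1.11, two-sided exact permutation p = 0.0286, the smallest possible here).

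DNA repair genes fell as well, with 25 of 32 lower, 1 higher and 6 not passing (median −0.46, camera adjusted p = 3.89e-06; adjusted p = 0.336 with an estimated correlation). RAD54L (−1.02 ± 0.09), BRCA1 (−0.74 ± 0.07) and FANCD2 (−0.73 ± 0.06), genes of homologous recombination and crosslink repair, were examples. Among replication-dependent histone genes, which yield mostly non-polyadenylated mRNA, 8 of 13 tested were higher, 1 was lower and 4 did not pass (median 0.55, camera adjusted p = 0.00727; adjusted p = 0.0953 with an estimated correlation). H2AC6 rose by 1.88 ± 0.12, H2AC11 by 1.44 ± 0.15 and H3C10 by 1.27 ± 0.19, and H2AC20 was lower (−0.51 ± 0.20, adjusted p = 0.037), a call that ended with DESeq2 and without control replicate 2 or 4 or inhibitor replicate 2 or 3 (adjusted p up to 0.155). Reads can be shared between copies of these histone genes. The p53 target list was not called, with 6 of 30 members higher, 16 lower and 8 not passing (camera adjusted p = 0.0584), and with 9 higher and 12 lower under total counts. CDKN1A, which encodes the cell cycle inhibitor p21, fell (−0.70 ± 0.06), as did the stress cytokine gene GDF15 (−1.88 ± 0.07).

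ATF4 target genes and genes of ER chaperones fell more often than they rose. Of 35 ATF4 target genes, 25 were lower, 1 was higher and 9 did not pass (median −0.46, camera adjusted p = 3.83e-07; adjusted p = 0.0779 with an estimated correlation), including STC2 (−1.95 ± 0.12), the alanine aminotransferase gene GPT2 (−1.28 ± 0.06) and the amino acid transporter gene SLC7A5 (−1.26 ± 0.06). Of 28 genes of ER chaperones and the unfolded protein response, 17 were lower, 5 higher and 6 not passing (median −0.41, camera adjusted p = 0.000711; adjusted p = 0.336 with an estimated correlation). The chaperone gene HSPA5 fell from 849.4 ± 16.1 to 354.2 ± 20.6 CPM (−1.26 ± 0.06), MANF (−1.32 ± 0.06) and PDIA4 (−1.18 ± 0.06) fell, whereas the stress sensor genes ATF6 (0.70 ± 0.08) and ERN1 (0.50 ± 0.09) rose. Heat shock genes were not called, with 4 higher, 10 lower and 6 not passing (camera adjusted p = 0.266), and with 8 higher and 7 lower under total counts, so no direction is given for them.

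Lysosome and autophagy genes rose. Of 43, 33 were higher, 1 was lower and 9 did not pass (median 0.36, camera adjusted p = 3.83e-07; adjusted p = 0.0545 with an estimated correlation). The autophagosome gene GABARAPL1 rose by 1.27 ± 0.09, the autophagy receptor gene SQSTM1 by 0.84 ± 0.06, the sialidase gene NEU1 by 0.84 ± 0.06 and the protease gene CTSB by 0.77 ± 0.06. TFEB, which encodes a transcriptional activator of lysosomal genes, was the member that fell (−0.58 ± 0.12, adjusted p = 0.000145). Interferon-responsive genes were higher in 21 of 34 cases, lower in 4 and not passing in 9 (median 0.55, camera adjusted p = 0.00146; adjusted p = 0.075 with an estimated correlation). IRF7 (1.27 ± 0.11), STAT2 (0.80 ± 0.07) and the peptide transporter gene TAP1 (0.72 ± 0.07) rose, and IFITM2 fell (−1.63 ± 0.13). All 6 tested metallothionein and zinc-responsive genes rose (median 1.22, camera adjusted p = 0.00102; adjusted p = 0.075 with an estimated correlation), among them MT1E (1.64 ± 0.11) and MT2A (1.05 ± 0.08), which are members of a family of similar sequences.

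**Figure D3:**
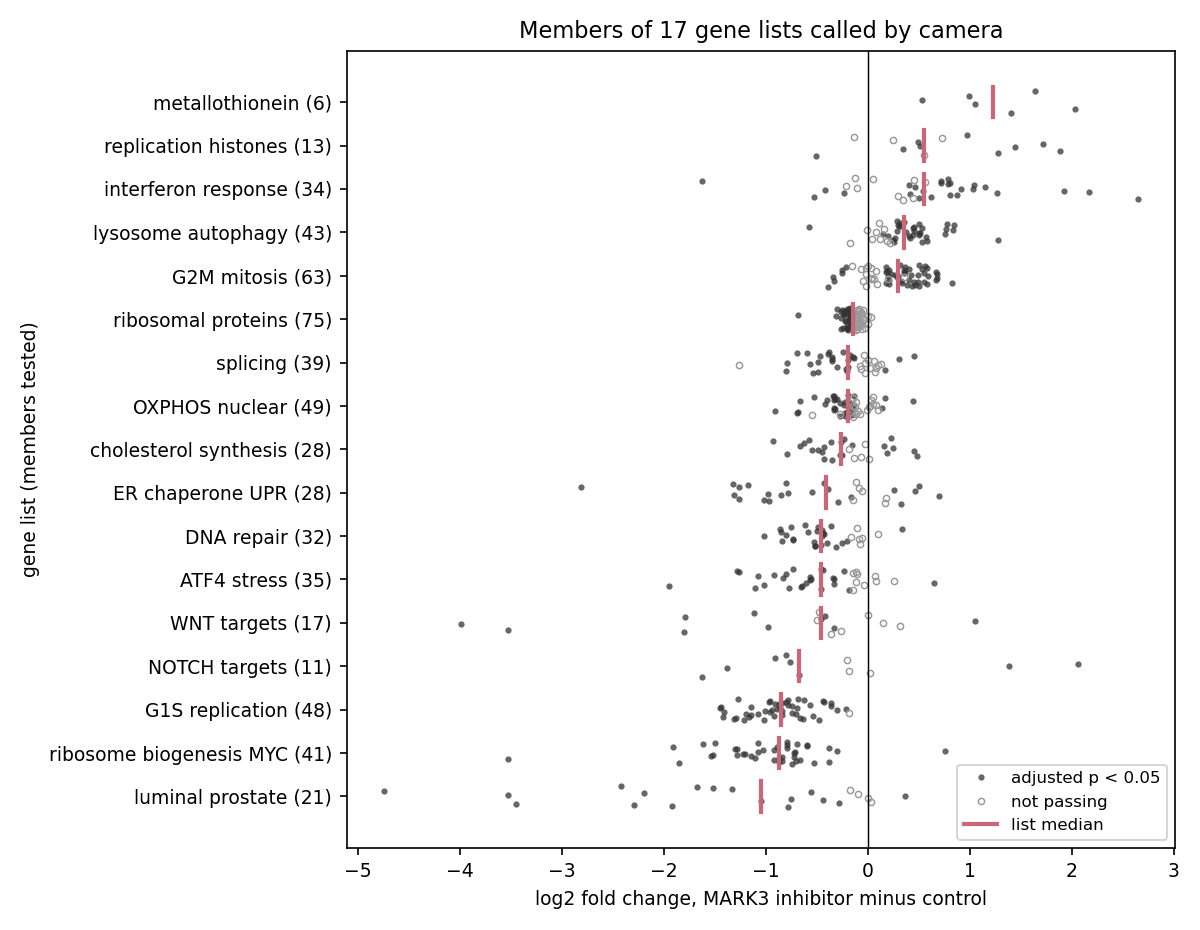
Log2 fold change (inhibitor minus control, horizontal axis) of every tested member of 17 of the 18 gene lists called by camera, with the number of tested members in brackets. Filled points passed the gene test, open points did not, and red lines are list medians, from −1.05 for luminal prostate markers to 1.22 for metallothioneins. All 17 medians keep their sign with total counts in place of TMM factors.

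Lists of cholesterol synthesis, oxidative phosphorylation, splicing, WNT target and NOTCH pathway genes were also called lower. Cholesterol synthesis genes were lower in 17 of 28 cases and higher in 6 (median −0.26, camera adjusted p = 0.0103; adjusted p = 0.513 with an estimated correlation), and in 13 and 6 with a median of −0.155 under total counts. TMEM97 (−0.93 ± 0.06) and SQLE (−0.58 ± 0.06) fell. Nuclear genes of oxidative phosphorylation were lower in 28 of 49 cases and higher in 3 (median −0.20, camera adjusted p = 0.000989; adjusted p = 0.725 with an estimated correlation), with 17 lower, 8 higher and a median of −0.096 under total counts. ATP5F1D, an ATP synthase subunit gene, fell (−0.91 ± 0.07). Splicing genes were lower in 23 of 39 cases and higher in 3 (median −0.20, camera adjusted p = 0.00207; adjusted p = 0.318 with an estimated correlation), with 15 lower, 7 higher and a median of −0.091 under total counts. SNRPD1 (−0.80 ± 0.06) and SRSF1 (−0.79 ± 0.07) fell. WNT target genes were lower in 9 of 17 cases and higher in 1 (median −0.46, camera adjusted p = 0.00385; adjusted p = 0.0779 with an estimated correlation), and with the GC adjustment 7 were lower, 3 were higher and the median was −0.232. LGR5, which encodes an R-spondin receptor, was at −3.99 ± 0.14 and the adhesion gene CD44 at −1.12 ± 0.06. LGR5 overlaps the strongly expressed TSPAN8 on the opposite strand. Of 11 NOTCH pathway genes, 6 were lower and 2 higher (median −0.68, camera adjusted p = 0.0494; adjusted p = 0.494 with an estimated correlation), a call that also ended with RLE normalisation, with no filter (median −0.20) and without any of control replicates 1 to 4 or inhibitor replicate 1 or 2 (adjusted p up to 0.147). HES1 (−1.63 ± 0.08), HES4 (−1.38 ± 0.08) and NOTCH3 (−0.91 ± 0.07) fell.

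Other genes with large changes lay outside these lists. Among the 10 largest rises in genes of at least 10 CPM, DHRS2 (chromosome 14, 23630115 to 23645639, plus strand) rose from 24.96 ± 1.09 to 210.7 ± 22.2 CPM (3.08 ± 0.08, adjusted p = 2.25e-20). The potassium channel gene KCND1 rose by 2.66 ± 0.14, NAP1L3 by 2.19 ± 0.13 and the RNA-editing enzyme gene ADARB1, which overlaps the pseudogene SSR4P1 on the opposite strand, by 2.05 ± 0.08. SEMA3E rose by 1.95 ± 0.12, the lysine catabolism gene AASS by 1.84 ± 0.12 and IQCN by 1.81 ± 0.12. FEZF1 (2.09 ± 0.12) and MC1R (1.82 ± 0.12) also ranked there, but overlap the antisense gene FEZF1-AS1 and the gene TCF25 respectively. Among the largest falls, TNC, which encodes the matrix protein tenascin-C (chromosome 9, 115019575 to 115118207, minus strand), dropped from 74.5 ± 6.85 to 3.15 ± 0.734 CPM (−4.59 ± 0.12, adjusted p = 2.26e-20). TRGC1, a T-cell receptor gamma constant gene whose locus gives rise to a transcript known in prostate cells, fell (−4.47 ± 0.15). The calcium-activated potassium channel gene KCNMA1 (−3.62 ± 0.14), the nicotinic receptor gene CHRNA2 (−3.28 ± 0.08) and the proline synthesis gene PYCR1 (−2.73 ± 0.07) also fell. HLA-E (2.83-fold higher) and PBXIP1 (1.21 ± 0.06) were among the 5 rises with the smallest p.

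Of 46 lists, 45 had enough tested members and 18 were called by camera, 13 lower and 5 higher. With an estimated correlation, 2 calls held, those of the ribosome biogenesis and luminal prostate lists. Fatty acid synthesis genes (6 higher, 13 lower of 25, or 9 and 11 under total counts; camera adjusted p = 0.17) were not called, although FASN fell from 1897 ± 52.9 to 787.0 ± 74.5 CPM (−1.27 ± 0.06), and FADS2 (−1.54 ± 0.06) and SCD (−0.86 ± 0.07) fell too. PI3K and FOXO pathway genes (15 higher, 9 lower of 29; adjusted p = 0.197) included rises of CCNG2 (1.17 ± 0.07) and CDKN1B (0.80 ± 0.05), which encodes the cell cycle inhibitor p27. Immediate early genes (14 higher, 9 lower of 28; adjusted p = 0.355) included rises of FOS (1.79 ± 0.11), EGR1 (1.47 ± 0.09) and JUN (0.73 ± 0.06). Neuroendocrine genes (6 higher, 6 lower of 17, or 8 and 4 under total counts; adjusted p = 0.96) included falls of SYT4 (−1.65 ± 0.07) and SRRM4 (−1.05 ± 0.07) and rises of PEG10 (1.19 ± 0.06) and POU3F2 (0.92 ± 0.10). YAP and TEAD targets (7 higher, 7 lower of 22, or 10 and 6 under total counts; adjusted p = 0.856) included a fall of CCN2 (−1.72 ± 0.09).

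The remaining lists were not called by camera. Members were higher and lower in 8 and 16 of 36 glycolysis and hypoxia genes (adjusted p = 0.189), in 7 and 11 of 26 fatty acid oxidation genes (0.351), and in 9 and 16 of 37 actin cytoskeleton genes (0.206). The corresponding counts were 14 and 11 of 38 microtubule genes (0.362), 7 and 11 of 31 proteasome genes (0.536), 4 and 8 of 17 CREB targets (0.412), 7 and 7 of 24 apoptosis genes (0.669) and 0 and 2 of 16 NF-kB genes (0.613). For NRF2 targets they were 8 and 8 of 23 (0.722), for TGF-beta and epithelial-mesenchymal genes 13 and 7 of 30 (0.722), for basal and stem cell genes 5 and 5 of 12 (0.722), for ERK feedback genes 3 and 5 of 18 (0.77) and for AhR and xenobiotic genes 4 and 4 of 11 (0.794). Median and mean differed in sign for the NRF2, TGF-beta, basal, ERK, YAP and neuroendocrine lists, so no direction is given for them. With total counts the medians of the fatty acid oxidation, actin, proteasome and NF-kB lists changed sign. The counts higher and lower were then 13 and 15 for glycolysis and hypoxia, 9 and 8 for fatty acid oxidation, 11 and 13 for actin, 20 and 8 for microtubule, 11 and 4 for proteasome, 2 and 2 for NF-kB and 6 and 4 for ERK feedback genes, so these balances depend on the scaling.

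Control and marker lists were not called by camera. Of 25 housekeeping genes, 6 were higher and 12 lower, with a median of −0.10 that became 0.00 with total counts (camera adjusted p = 0.186). Of 13 mitochondrially encoded genes, 6 were lower and 7 did not pass (adjusted p = 0.186), with 1 higher and 2 lower under total counts, and their summed level was 56560 ± 410 CPM in controls and 56130 ± 1040 CPM in treated libraries (mean ± SD, n = 4). Nuclear and small nucleolar host RNAs used as signs of RNA quality summed to 1574 ± 114 and 1534 ± 70.9 CPM, with 4 of 9 lower and 5 not passing (adjusted p = 0.17). Fibroblast markers summed to 54.8 ± 2.80 and 69.0 ± 11.5 CPM, with 3 of 7 higher and 3 lower (adjusted p = 0.696), among them TAGLN (1.18 ± 0.16) and LUM (−2.62 ± 0.29). Immune and endothelial markers, too few for a set test, summed to 10.3 ± 1.59 and 5.35 ± 1.79 CPM, mostly from HBA1 (−1.53 ± 0.31, adjusted p = 0.000912).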

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

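Of 328 groups of 4 values examined, 8 had a library far from the other 3 by Dixon's ratio of gap to range, and chance alone would mark about 1 group in 20. The tests of copy number and of the G1/S and G2/M lists each alone below were chosen only after the results were seen, and the GC adjustment and thinning were added after seeing the data.

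The total count of inhibitor replicate 2 was 21270000, against 13520000 to 14220000 in the other treated libraries (ratio 0.91). In inhibitor replicate 3, HLA-E was lowest at 81.61 CPM against 94.21 to 96.06 (0.872), TFEB at 8.827 against 10.37 to 10.47 (0.938), and MT1E at 16.04 against 17.85 to 18.2 (0.834). STAT2 was lowest in inhibitor replicate 1 at 71.45 CPM against 80.69 to 82.34 (0.848). Among controls, SEMA3E was lowest in replicate 4 at 4.837 CPM against 6.642 to 6.891 (0.879), GDF15 was highest in replicate 4 at 68.97 against 65.52 to 65.9 (0.889), and TRGC1 was lowest in replicate 2 at 42.3 against 52.66 to 53.8 (0.901). The gap for each of these 7 genes is smaller than its difference between the groups.

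The breadth of the response, 9549 genes, was weighed against technical explanations. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes, and the highest other split gave 1. Every other split mixes control and treated libraries, so a group difference of any origin would give this outcome. The splits show that the difference follows the groups, but cannot exclude that it arose by chance between cultures. The deeper library is not the cause of the count, since 98.6% of it was reached after thinning all libraries to the lowest total, and neither is the trend with transcript GC content, since the count after its removal was 102.6% of the original. Regional copy number differences between the cultures would move neighbouring genes together. Of the called protein-coding genes on the autosomes and X, 97.9% lie in runs of 50 neighbouring genes whose median is within 0.3. Only 7 of all 275 runs lay beyond 0.3, so nearly all runs were within it whatever their calls. Shifts of whole runs thus do not account for most calls. Copy changes of smaller regions or in a part of the cells could pass unseen. A broad effect of the treatment on the transcriptome is the hypothesis that stays open, while differences in culture or handling that coincide with the groups, of which the labels say nothing, were not tested.

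The opposite movement of G1/S and G2/M genes was weighed in the same way. The difference between the medians of the G2/M and G1/S lists was 91.7% of its value after the GC adjustment and 101.1% after thinning, so neither GC content nor depth is the whole cause of the difference. Taken alone, the G1/S median was 101.6% of its value after the GC adjustment, but the G2/M median was 62.9%, so a part of the G2/M rise cannot be told apart from the GC trend, although the list was still called at the preset correlation (camera adjusted p = 0.00103; without the GC adjustment, adjusted p = 0.494 with an estimated correlation). As a hypothesis, a larger share of cells in G2 or mitosis may underlie the opposite movement. Lower transcription of E2F targets may underlie the fall of the G1/S genes, but would not raise the G2/M genes. Neither was tested, and counts from whole cultures hold no measure of cell cycle phase that could separate them.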

How the results depend on the processing

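The GC adjustment, the surrogate variable, thinning and the shortened lists were chosen after seeing the data. At an adjusted p under 0.05, the number of genes changed ranged from 8867 (without control replicate 3) to 9870 (total counts) over the alternatives, against 9549. Of the original calls, 88.9% (total counts) to 99.7% (no robust dispersion) were shared, all with the same sign. DESeq2 called 9096, limma-voom 9516, no filter 9783 and the GC adjustment 9801 genes. A minimum log2 change of 1 left 1700 genes, 698 higher and 1002 lower, by construction. MARK3 kept its call in all 20 alternatives (log2 0.18 to 0.32).

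The number of lists called by camera went from 18 to 2 with an estimated correlation and to 42 with fry, which asks another question. With the estimated correlation the adjusted p was 0.075 for the interferon and for the metallothionein list and 0.494 for the G2/M list, which kept its call in the other alternatives. The NOTCH list lost its call in most alternatives, with the highest p of 0.147 among the libraries left out (without control replicate 4).

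Of 2200 values of 110 genes followed through the alternatives, 2187 kept direction and side of the threshold, and 107 genes did so in every alternative. Most of these genes were picked by the rule for a small p or a large change in the same libraries. They were therefore likely to keep their calls. The MARK2 log2 fold change, near 0 in the report, reversed to −0.00155 without control replicate 1, to −0.000286 without inhibitor replicate 2 and to −0.00433 with 1 surrogate variable, passing the test in none of these, and ranged up to 0.0571 with a library left out (without control replicate 4). RPL8 went from −0.301 to −0.146 and lost its call with the GC adjustment (adjusted p = 0.0607 in edgeR), and H2AC20 in 9 alternatives, and the cause was not tested.

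With the replicate block 9596 genes were called, 9413 of them shared. Samples with the same number had correlations of their deviations of 0.131, −0.088, −0.053 and 0.084. Not every sample correlated best with its own number, so the numbers were not taken to pair the samples. The second principal component (7.4% of the variance) ran across the groups. Control replicates 1 and 2 and inhibitor replicates 1 and 3 scored 7 to 16.85, the other libraries −14.37 to −10.9. Correlations between control and inhibitor libraries were positive within each set (0.027 to 0.131) and negative between sets (−0.161 to −0.053). Across genes, the loadings of this component had a Spearman rho of −0.485 with transcript GC content, so the split went along with GC content. Genes are not independent replicates. The main test held no term for this split. The GC adjustment called 9801 genes and the fit with 1 surrogate variable 9409. Whether that variable follows the split was not examined, and what gave rise to the split was not tested. The block ended the call of the NOTCH list (adjusted p = 0.0627 with camera). Simulated genes changed 2-fold were recovered in 93.9% of cases and smaller changes less often.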

Other observations

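The genes and groups in this part were picked for it after their values were seen, as was the test of the list in its last paragraph.

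Clustered protocadherin genes, which encode neuronal adhesion proteins from a shared locus on chromosome 5 (140786136 to 141512977, hg38), were higher in 27 of 46 tested cases and lower in none, with a median log2 change of 0.59, or 0.54 after the GC adjustment. Of all 16452 tested genes, 4897 were higher and 4652 lower. The alpha, beta and gamma clusters had 11 of 15, 6 of 14 and 10 of 17 members higher. Levels were low, with a median of 2.32 CPM in controls. PCDHB2 and PCDHGC3, the members with the highest mean levels (16.5 and 14.6 CPM), did not pass (0.002 and −0.204). The members next in level, PCDHA10 and PCDHA13 (13.9 and 13.7 CPM), rose (0.442 and 0.707). Many of these gene models overlap and share exons, so their counts are not independent. A run of 50 neighbouring genes that overlaps this locus (140807037 to 141879246) was among the 7 runs beyond 0.3 in the copy number check above. Its median of 0.551, with 26 genes higher and 2 lower, was the furthest from 0 of all runs. A regional copy number difference at this locus therefore cannot be told apart from a change in expression here. HLA-B and HLA-C rose with HLA-E, by 0.87 ± 0.15 and 0.46 ± 0.07 on the log2 scale. These genes are highly polymorphic, and read assignment among them is uncertain. The mitochondrial 16S rRNA gene MT-RNR2 was higher (0.43 ± 0.06, adjusted p = 3.67e-06 in edgeR) whereas MT-RNR1 was not called (−0.02 ± 0.18, adjusted p = 0.945).

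Among regulators of the prostate lineage, GATA2 fell from 112.4 ± 1.98 to 29.6 ± 2.14 CPM (log2 −1.92 ± 0.07, mean ± SD of 4 libraries per group for the levels) and HOXB13 was lower (−0.29 ± 0.05), whereas FOXA1 was at 482.8 ± 20.2 and 484.3 ± 17.8 CPM. CCND1 was at 2806 ± 132 and 2804 ± 138 CPM while MYC and the E2F genes fell. MXD4, which encodes a MAX partner that opposes MYC, rose by 1.08 ± 0.06.

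MYC was lower while HEXIM1 (2.11-fold), SERTAD1 (2.37-fold) and several histone transcripts were higher, a combination known from inhibition of BET bromodomain proteins, and as a hypothesis the treated cells may share part of such a profile. Of a list with directions written from general knowledge, 5 members had not been seen beforehand once its histone genes, whose rise had prompted it, were left out, and of these ZCCHC24, BCL2 and MYB were called in the listed direction and HSPA2 and CDK6 in the other. Their signed median of 0.48 was at the 95.79 percentile of 10000 matched random lists, and so few genes going both ways leave the hypothesis open. The signed median of all 17 listed genes was 110.1% of its value after the GC adjustment, so GC content does not account for it. These values do not tell a BET-like response from other causes of lower transcription of MYC, since several listed genes are histone genes or follow MYC and the cell cycle, and no other compound was compared.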
